A study of Homo sapiens with 10 samples.

How the data were processed

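Gene expression was measured in cultured human gastric cancer cells on 10 single-channel arrays, each hybridised with biotin-labelled total RNA. A side population is the small set of cells that keeps little of a DNA-binding Hoechst dye because ATP-binding cassette transporters pump it out, and it is separated by flow cytometry from the dye-bright non-side population. The labels gave 4 arrays of side population cells (replicates a to d), 4 of non-side population cells (replicates a to d) and 2 of unsorted cells (replicates a and b). AGS and MKN 45 are established lines from gastric carcinomas. The origin label of all 10 arrays names both lines, the source label of 8 arrays names AGS, and the source label of side population replicates a and b names no line. Nothing in the labels said whether the replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

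The deposited values were intensities on a linear scale, 54675 probe sets per array, from 0.1 to 74993.2. The submitters' processing notes name GCOS 1.4 without its role or settings, and the algorithm is not given in the sources used here. The trimmed mean, with 2% of the values left out at each end, lay between 500.065 and 500.095 on every array, so the deposited intensities were already scaled to a common trimmed mean, and no further scaling was applied. No detection calls were used here. The constant 6.1, the 10th percentile of all intensities, was added before taking log2, so fold changes are on the log2(value + constant) scale and understate the change of genes with low intensity. Where a named gene that passed averaged less in a group than the medians of that group's arrays, the difference of the mean log2 values is also given with every value under its array's median raised to that median. This was added after the results were seen.

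Probe sets were named through the platform annotation: 41097 had 1 gene symbol, 1801 had several and 11777 had none. Of the first, 41043 matched the reference gene table through their gene identifier, and 0 symbols needed updating. Each gene was represented by the probe set of highest mean log2 value among those with exactly 1 symbol, which gave 19775 genes. The text says where other probe sets of a named gene differed in sign. Genes at or above the median of the mean log2 values were tested, which left 9888 genes and corresponds to an intensity of 149.

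Differences between groups were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a trend), with all 10 arrays and 3 groups in 1 fit and no covariate. Values of p were adjusted by Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05. Fold changes are given with the standard error of the fit. The number of arrays, above all the 2 of unsorted cells, limits the precision. No pair of arrays held identical values.

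Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast, and again with the correlation estimated from the data and with fry, a rotation test. A list needed 4 tested genes. The 25 lists held ABC efflux transporters, stem cell markers, Wnt pathway, Notch pathway, Hedgehog pathway, G1/S and DNA replication, G2/M and mitosis, p53 targets, immediate early genes, heat shock response, unfolded protein and amino acid stress, hypoxia and glycolysis, oxidative phosphorylation, cytosolic ribosomal proteins, gastric differentiation, intestinal differentiation, epithelial junctions and keratins, mesenchymal and fibroblast markers, blood and endothelial cell markers, interferon response, NF-kB and inflammatory genes, cholesterol synthesis, NRF2 and xenobiotic metabolism, MKN45-linked genes and nuclear-retained RNAs. Some members of the stem cell, Wnt, Notch and Hedgehog lists were picked by the study on these samples, so those lists are not independent evidence. Blood and endothelial cell markers (3 genes tested of 14 measured) and nuclear-retained RNAs (1 of 3) were too few to test, which left 23 lists.

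The groups, comparisons, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule named, for each contrast and direction, the 10 called genes of largest fold change whose groups did not overlap. Where fewer than 10 qualified, it named genes of smallest unadjusted p with a log2 fold change of at least 1 in size, given as values that did not pass. It also named up to 4 members of each list by smallest p, which could be left out where a list was only summarised, and 11 stem cell, pathway and transporter genes.

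The alternatives were another added constant or none, no filter and a filter at the 75th percentile, quantile normalization, every probe set on its own, eBayes without a trend, only the compared groups, only arrays whose source label names AGS, a fold threshold, leaving out each array, and the replicate letter as a block. After the data were seen, the arrays of letters a and b and those of letters c and d were also treated as 2 batches, with each contrast averaged over both and taken for each, since a split along these letters called the most genes. The letters of the unsorted arrays (UCPa and UCPb in the titles) are a series apart from those of the sorted arrays (SPa to SPd). Against unsorted cells the same 2 unsorted arrays served the sorted arrays of both batches, and the 2 values given for letters share these controls. The grouping into batches came from the data and not from the labels. Since it was picked for the differences it showed, fits with it may understate the residual spread. Their adjusted p-values may be too small and their counts too high.

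The steps were tested on simulated data with 200 changed genes among 9888. Noise was drawn independently for each gene and array, which the real arrays need not follow, so the shares called may be too high. Between side and non-side population, 36% of changes of 1 log2 unit and 94% of changes of 2 were called. The shares were 9% and 88% for side population against unsorted cells, and 5% and 89% for non-side population against unsorted cells. All called changed genes had the right sign in these 3 comparisons, and between 1 and 12 unchanged genes were called.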

Results

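The 10 arrays compared side population, non-side population and unsorted gastric cancer cells. Median intensity over all probe sets ranged from 58.7 to 85.4 between arrays. The ratio of 3' to 5' intensity, which rises when RNA is degraded or incompletely copied, was 3.34 for the actin control in side population replicate a and between 0.987 and 1.28 on the other 9 arrays. For GAPDH it was 1.87 in that array and between 0.864 and 1.06 elsewhere. The 5' control probe set for 18S ribosomal RNA read between 22182.4 and 33704 on 6 of the 8 sorted arrays. It read 851.2 in side population replicate d, 563 in non-side population replicate c, and 274.6 and 828.3 in unsorted replicates a and b. Across genes, which are not independent replicates, arrays of 1 group correlated at 0.883 to 0.987, side with non-side population arrays at 0.911 to 0.978, and sorted with unsorted arrays at 0.895 to 0.945. The first principal component, with 32.4% of the variance, spread the sorted arrays from -29.3 (non-side population replicate c) to 52 (non-side population replicate b), with the unsorted arrays among them at -22.9 and -14.3. The second, with 26%, placed the unsorted arrays at -42.1 and -38.8 and the 8 sorted arrays between -5.3 and 26.1.

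The central comparison asked which genes distinguish side population cells from the dye-retaining cells. No gene was called. The transcripts with the smallest p among those at least doubled in side population cells were UBE2O, a ubiquitin-conjugating enzyme (log2 fold change 1.23 ± 0.41, SE, n = 4 and 4), TTC38 (1.34 ± 0.58), KLHL25, an adaptor of a cullin ubiquitin ligase (1.03 ± 0.48), and HINT3 (1.00 ± 0.54). Lower values in side population cells were measured for BAX, which promotes apoptosis (-1.02 ± 0.27), DCLRE1C, the Artemis nuclease of DNA end joining (-1.01 ± 0.20), HIRA, a histone chaperone (-1.005 ± 0.28), the zinc finger gene ZNF652 (-1.99 ± 0.55) and CAPN10, a calpain protease (-1.03 ± 0.29). The same held for the noncoding genes MORC2-AS1 (-1.32 ± 0.34), SLC12A2-DT (-1.11 ± 0.27) and PSMD6-AS2 (-1.04 ± 0.29) and the pseudogenes SMG1P5 (-1.59 ± 0.32) and SDCBPP2 (-1.21 ± 0.31), whose probe sets may also bind their parent genes. None of these 14 genes passed the test. Other probe sets had the opposite sign for TTC38, HINT3, DCLRE1C, SLC12A2-DT, ZNF652, HIRA and CAPN10.

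By limma, 0 of 9888 genes differed between side and non-side population, with a smallest adjusted p of 0.992. At an unadjusted p under 0.05 there were 430 genes, 310 higher and 120 lower in side population cells, where chance gives 494. On simulated data for this comparison, 36% of changes of 1 log2 unit and 94% of changes of 2 were recovered.

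The arrays of letters a and b and those of letters c and d gave different pictures. This division was picked after the data were seen, since it called the most genes of the splits tried. Adjusted p-values from fits with it may therefore be too small. Within letters a and b, BAX was lower in side population cells by a log2 fold change of -1.77 ± 0.22 (adjusted p = 0.0106), ZNF652 by -3.11 ± 0.62 (adjusted p = 0.0226), and UBE2O was higher at 2.22 ± 0.44 (adjusted p = 0.0219; SE, n = 2 and 2). In letters c and d BAX was at -0.27 ± 0.22 (adjusted p = 0.998), and the difference from letters a and b did not pass (adjusted p = 0.0998). Limma called 905 genes within letters a and b (704 higher, 201 lower) and 0 within letters c and d (smallest adjusted p 0.317, 437 genes at an unadjusted p under 0.05). Of the 905, 346 (38.2%) had the same sign in letters c and d, so most had the opposite sign there. Turned to the sign in letters a and b, the median log2 fold change of the 905 in letters c and d was -0.07. By limma 0 genes passed the test of the difference between the 2 batches (smallest adjusted p 0.0947, 2655 genes at an unadjusted p under 0.05). Without side population replicate a, the array with the raised 3' to 5' ratios, 1 gene was called in letters a and b, and 0 of the 905 were. The count was 0 without non-side population replicate b, 561 without side population replicate b and 531 without non-side population replicate a, each time with a population of 1 array that was assumed to vary like the other groups. Without each of these 4 arrays at least 901 of the 905 genes kept their sign. Their median log2 fold change, 0.98 with all arrays, was 0.90 and 1.04 without side population replicates a and b and 1.01 and 0.93 without non-side population replicates a and b. The median SE rose from 0.24 to 0.29. The 905 genes were picked on these same 4 arrays, so kept signs and similar medians were likely from the start. They are no support for the calls. The side population arrays of letters a and b are the 2 whose source label names no line, while all other arrays are labelled AGS, so within letters a and b the populations and this label cannot be told apart. Averaged over both batches, limma called 0 genes (smallest adjusted p 0.106). At an unadjusted p under 0.05 this fit had 1279 genes, where chance gives 494 and the fit without batches had 430.

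No gene of the set tied to stem cells and dye efflux passed the test between side and non-side population cells. FZD7, a Wnt receptor, had an intensity of 3430 ± 768 in side population and 2378 ± 550 in non-side population cells (SD, n = 4 each), against 1593 ± 63.3 in unsorted cells (n = 2). Its log2 fold change between the sorted populations was 0.53 ± 0.23 (adjusted p = 0.997), with 0.86 ± 0.24 (adjusted p = 0.0458) in letters a and b and 0.19 ± 0.24 (adjusted p = 0.998) in letters c and d, and the difference of these did not pass (adjusted p = 0.224). HEY1, a target of Notch, was at 0.02 ± 0.25, ADAM17, a protease that sheds membrane proteins, at 0.16 ± 0.20, the stem cell factor SOX2 at -0.32 ± 0.43, LGR5 at 0.26 ± 0.23 and CD44 at 0.07 ± 0.29. The other genes of this set lay below the expression filter and were tested only without it. ABCG2, the transporter most often linked to dye efflux, had a log2 fold change of 0.29 ± 0.67, ABCB1 of 0.03 ± 0.50, MSI1 of 0.09 ± 0.47 and SMO, the Hedgehog signal transducer, of 0.23 ± 0.35. PROM1, which encodes CD133, read 38.3 ± 10.7 in side population and 12.8 ± 12 in non-side population cells (SD, n = 4 each), a log2 fold change of 1.46 ± 0.49 with an adjusted p of 0.977. Some of these genes were picked by the study on these samples.

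**Figure D1:**
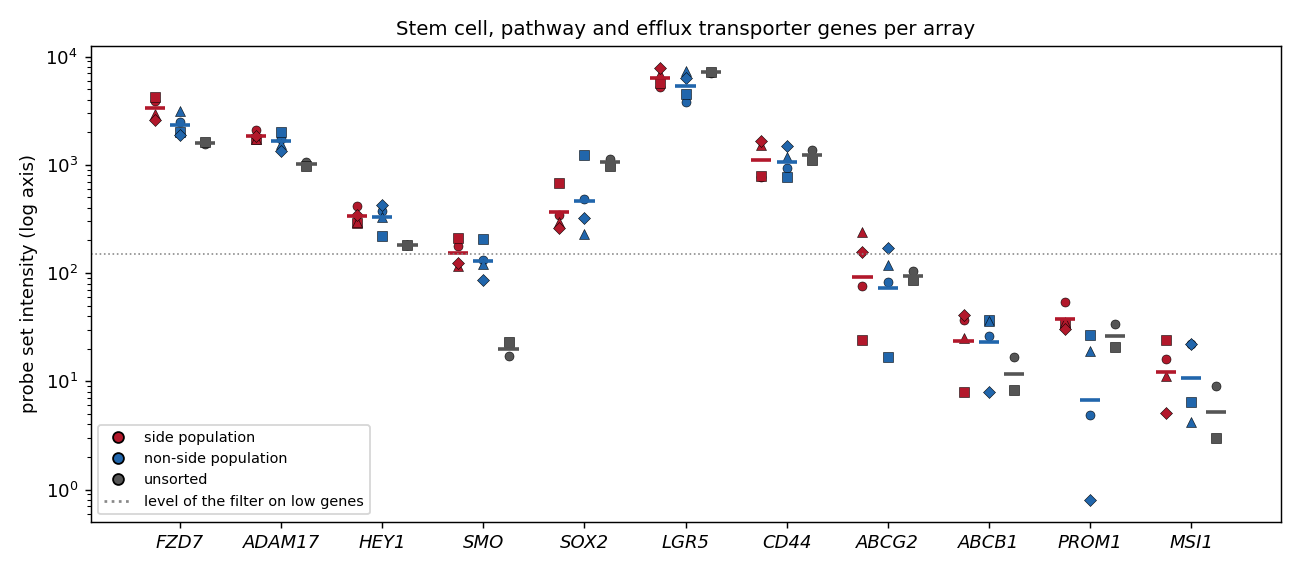
Probe set intensity on a log axis for 11 stem cell, pathway and efflux transporter genes, with 1 point per array, the marker shape giving the replicate letter (circle a, square b, triangle c, diamond d), and horizontal bars for geometric means. The letters of the unsorted arrays are a separate series. The dotted line marks the filter level of 149. SMO averaged 158.1 and 136.2 in the sorted populations and 20.15 in unsorted cells.

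The list of G2/M and mitosis genes was called lower in side population than in non-side population cells by camera at the preset correlation, and by no other list test run. Of 40 G2/M and mitosis genes, 33 had a negative fold change and 7 a positive one, with a median of -0.12 and a mean of -0.20 on the log2 scale. The members of smallest p were CENPA, the centromeric histone variant (-0.76 ± 0.23), PLK1, a mitotic kinase (-0.76 ± 0.31), AURKB, another mitotic kinase (-0.59 ± 0.24), and NDC80, of the kinetochore (-0.57 ± 0.22), and 0 members were called, also when adjusted over the list alone. Camera gave an adjusted p of 1.17e-06 at the preset correlation. The call was lost with an estimated correlation (adjusted p = 0.946) and with fry (adjusted p = 0.994). Within letters a and b the adjusted p was 0.852 and the median 0.15, with 3 members called higher and 2 lower although the test pointed down, and within letters c and d they were 1.15e-17 (0.537 with an estimated correlation) and -0.44. Without side population replicate d the adjusted p was 0.0589.

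The other 22 lists were not called between side and non-side population. Of 18 Wnt pathway genes 14 had positive values (adjusted p = 0.412), with CCND1 at 0.59 ± 0.30 and FZD2 at 0.57 ± 0.28. Among 20 Notch pathway genes 14 were positive (adjusted p = 0.807), with NOTCH1 at 0.49 ± 0.24 and JAG1 at 0.40 ± 0.18. The adjusted p was 0.882 for ABC efflux transporters, 0.865 for stem cell markers, 0.865 for the Hedgehog pathway, 0.882 for G1/S and DNA replication, 0.905 for p53 targets, 0.235 for immediate early genes and 0.892 for the heat shock response. It was 0.905 for unfolded protein and amino acid stress, 0.865 for hypoxia and glycolysis, 0.614 for oxidative phosphorylation, 0.807 for cytosolic ribosomal proteins, 0.865 for gastric and 0.807 for intestinal differentiation. It was 0.905 for epithelial junctions and keratins, 0.588 for mesenchymal and fibroblast markers, 0.588 for the interferon response, 0.938 for NF-kB and inflammatory genes, 0.905 for cholesterol synthesis, 0.394 for NRF2 and xenobiotic metabolism and 0.865 for MKN45-linked genes. BAX alone passed when adjusted over the list alone, among 24 p53 targets. The test pointed down while the median was at or above 0 for p53 targets, unfolded protein and amino acid stress, oxidative phosphorylation, cytosolic ribosomal proteins and epithelial junctions. The number of lists called, 1 with all arrays, was 3 without side population replicate c and 2, 5 and 3 without non-side population replicates a, b and c. Cytosolic ribosomal proteins were called in the last (adjusted p = 9.31e-14, down). The array left out there was apart on this list, at a mean log2 value of 14.28 against 15.13 to 15.22. Without side population replicate d the 1 list called by camera was not G2/M and mitosis (adjusted p = 0.0443). These fits used the preset correlation only. The oxidative phosphorylation genes were lower in side population cells within letters a and b (median -0.31, adjusted p = 7e-07) and higher within letters c and d (median 0.33, adjusted p = 2.25e-12), with an adjusted p of 0.942 and 0.92 with an estimated correlation. The Hedgehog pathway was called lower within letters c and d (median -0.39, adjusted p = 0.049, and 0.647 with an estimated correlation).

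Between side population and unsorted cells 232 genes were called, of which 77.2% were higher in side population cells. The largest fitted increases were in BST2, an interferon-induced membrane protein that tethers viruses (log2 fold change 4.41 ± 0.74, SE, n = 4 and 2), FGB, the fibrinogen beta chain (4.08 ± 0.47), SOD2, a mitochondrial superoxide dismutase (3.73 ± 0.83), IFI27 (3.23 ± 0.43) and IFI6 (2.94 ± 0.53), both interferon-induced, and CXCL8, which encodes interleukin 8 (3.20 ± 0.41). TXNIP, an inhibitor of thioredoxin (3.04 ± 0.33), the lipase gene CEL (2.93 ± 0.55), MIR7-3HG, a microRNA host gene (2.77 ± 0.32), and REM2, a small GTPase (2.73 ± 0.39), rose as well. Of these, FGB, CEL, MIR7-3HG and REM2 averaged 15.9, 44.6, 35.25 and 28.9 in unsorted cells, below the array medians of 60.9 and 58.7, so the size and order of their changes depend on the settings. With every value under its array's median raised to that median, they were at 2.31, 1.93, 2.10 and 1.70. FGB ranged from 3.33 to 4.83 and CEL from 1.73 to 4.12 over the alternatives, the ends for CEL being without unsorted replicate b and without a. The largest decreases were in FADD, an adaptor of death receptors (-2.34 ± 0.40), SP5, a transcription factor induced by Wnt signals (-2.30 ± 0.45), CENPB (-2.09 ± 0.31) and CENPI (-1.92 ± 0.47), both of the centromere, and ID1, an inhibitor of differentiation factors (-2.05 ± 0.43). MVD (-2.08 ± 0.34) and DHCR7 (-2.06 ± 0.43), enzymes of cholesterol synthesis, PLK1 (-1.99 ± 0.38), FRMD4B (-1.87 ± 0.30) and GPATCH2L (-1.83 ± 0.38) also fell. Other probe sets of FRMD4B and GPATCH2L reached 1.80 and 2.02.

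By limma 232 of 9888 genes were called between side population and unsorted cells, 179 higher and 53 lower, and 227 changed by at least 1 log2 unit. The count rested on the few unsorted arrays: it was 10 without unsorted replicate a and 17 without b, 95, 115 and 131 without side population replicates a, b and c, 385 and 355 without non-side population replicates b and c, and 90 with only AGS-labelled arrays. FGB, TXNIP and MIR7-3HG kept an adjusted p under 0.05 in all alternatives that tested them. With letters as batches the count was 1327, with 1359 for the side population arrays of letters a and b and 840 for those of letters c and d, each set against the same 2 unsorted arrays.

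Cholesterol synthesis genes fell together in side population cells relative to unsorted cells. All 15 tested members were negative, with a median log2 fold change of -1.01; 6 were called, and 10 were when adjusted over the list alone. Examples were SQLE, squalene epoxidase (-1.46 ± 0.24), and LSS, lanosterol synthase (-1.23 ± 0.25). Camera gave an adjusted p of 1.86e-11, and 0.0275 with an estimated correlation (0.125 with letters as batches). The median was -0.93 for letters a and b and -1.05 for letters c and d, which are not independent since the unsorted arrays are shared. Immediate early genes, which respond to growth factors and stress, were called higher as a list at the preset correlation: 22 of 22 were positive with a median of 0.90, 4 were called (13 adjusted over the list alone), and EGR1 was at 1.81 ± 0.34, IER3 at 1.73 ± 0.23, ATF3 at 0.94 ± 0.22 and DUSP1 at 0.90 ± 0.22. Their adjusted p was 7.99e-09, and 0.112 with an estimated correlation; the medians for letters a and b and for letters c and d, 0.70 and 0.73, share the unsorted arrays too. Of 17 interferon response genes 16 were positive, with a median of 0.91 and a mean of 1.54, and 4 were called (9 adjusted over the list alone): BST2, IFI27, IFI6 and IFI44 (2.41 ± 0.54). The adjusted p was 2.96e-07, and 0.721 with an estimated correlation. For letters a and b the interferon median was 0.41 with 6 genes called (adjusted p = 0.0205, and 0.89 with an estimated correlation), and for letters c and d it was 1.59 with 14 called (6.49e-15 and 0.179), a difference that was not tested.

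The other called lists held mitotic and ribosomal protein genes. Of 40 G2/M and mitosis genes 32 were negative in side population relative to unsorted cells, with a median of -0.29, and PLK1 alone was called (2 genes adjusted over the list alone). The adjusted p of the list was 5.22e-05, and 0.864 with an estimated correlation. It was 0.448 for letters a and b and 2.64e-12 for letters c and d (0.209 with an estimated correlation). All 52 cytosolic ribosomal protein genes were positive with a median of 0.21 and 0 called, RPL27A being highest at 2.62 ± 0.94. In log2 intensity RPL27A read 9.442 in side population replicate d, the array with low 18S signal. It read between 10.51 and 12.49 in the other side population arrays. Their adjusted p was 0.0106, 0.956 with an estimated correlation and 0.815 after quantile normalization. It was 0.0957 without side population replicate a, 0.138 without unsorted replicate b, 0.52 with only AGS-labelled arrays and 0.528 for letters c and d. For the 18 lists not called the adjusted p ranged from 0.152 to 0.989. Of these, oxidative phosphorylation was called lower for letters a and b (adjusted p = 0.0324, and 0.947 with an estimated correlation) and G1/S and DNA replication lower for letters c and d (0.0432 and 0.471). Gastric differentiation was called higher for letters c and d and with letters as batches, as given further below.

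**Figure D2:**
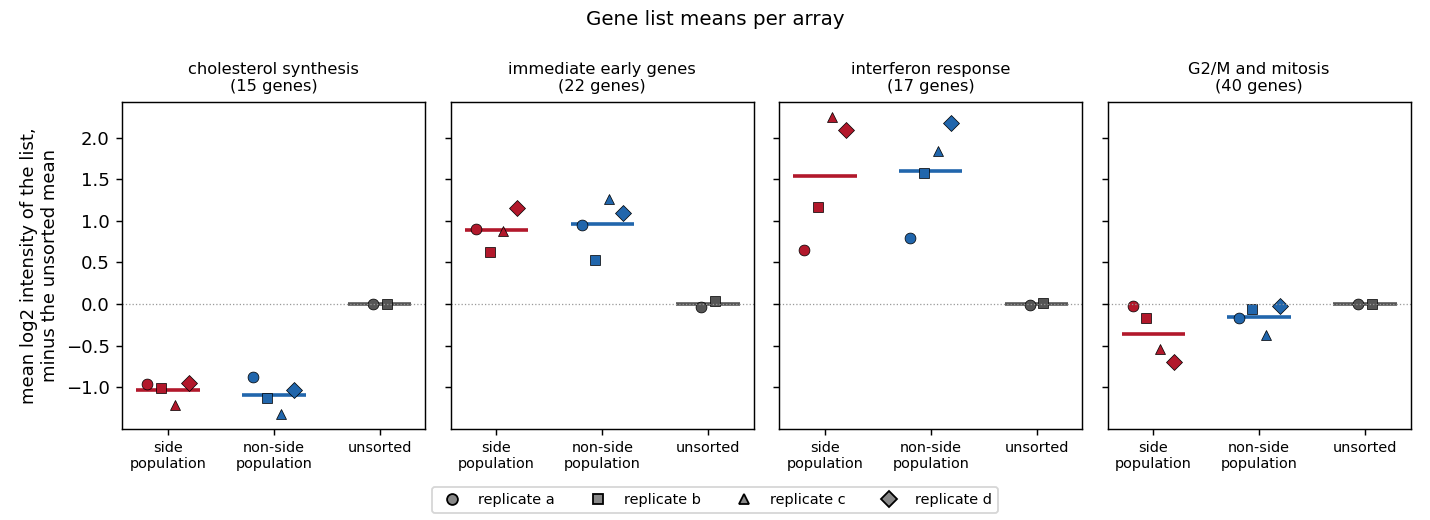
Mean log2 intensity of the tested genes of 4 lists on each array, minus the mean of the unsorted arrays, with 1 point per array, the marker shape giving the replicate letter, and bars for group means. The letters of the unsorted arrays are a separate series. Cholesterol synthesis lay below and immediate early and interferon response genes above the unsorted arrays on all 8 sorted arrays. G2/M and mitosis genes averaged 11.34 in side population, 11.54 in non-side population and 11.70 in unsorted cells.

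Non-side population cells differed from unsorted cells in many of the genes named for the side population. The largest fitted increases were in BST2 (log2 fold change 4.58 ± 0.74, SE, n = 4 and 2), FGB (4.16 ± 0.47), the interferon-induced genes IFI44L (3.67 ± 0.85), IFI27 (3.44 ± 0.43) and IFI6 (3.00 ± 0.53), LOC114224 (3.54 ± 0.43), MIR7-3HG (3.26 ± 0.32), SOD2 (3.25 ± 0.83), CXCL8 (3.14 ± 0.41) and the zinc finger gene ZNF493 (3.09 ± 0.54). With values raised to the array medians, FGB was at 2.39, MIR7-3HG at 2.59 and IFI44L, which averaged 46.5 in unsorted cells, at 3.32. The largest decreases were in SP5 (-2.69 ± 0.45), TMEM52B (-2.54 ± 0.55), GATA6, a transcription factor of the gut endoderm (-2.28 ± 0.36), TENM3, a cell adhesion protein (-2.27 ± 0.50), and DHCR7 (-2.20 ± 0.43). FRMD4B (-2.09 ± 0.30), FADD (-2.02 ± 0.40), SQLE (-1.95 ± 0.24), DUSP4, a phosphatase that turns off MAP kinases (-1.93 ± 0.28), and AMD1, an enzyme of polyamine synthesis (-1.90 ± 0.40), also fell. Over the alternatives DUSP4 ranged from -2.05 to -1.01 and lost its call in 5 of 22 settings, and SOD2 ranged from 2 to 4.49. Another probe set of FRMD4B was at 1.12.

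By limma 348 of 9888 genes were called between non-side population and unsorted cells, 234 higher and 114 lower, and 333 changed by at least 1 log2 unit. The count was 20 without unsorted replicate a and 43 without b, 221, 651 and 219 without non-side population replicates a, c and d, and 185 with only the 2 compared groups. FGB, IER3, IFI27, LOC114224, MIR7-3HG and SQLE kept an adjusted p under 0.05 in all alternatives that tested them. With letters as batches the count was 1564, with 2198 for the non-side population arrays of letters a and b and 1179 for those of letters c and d, again against the same 2 unsorted arrays.

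The same 3 lists led this contrast. All 15 cholesterol synthesis genes were negative with a median of -1; 7 were called, 10 adjusted over the list alone, among them LSS (-1.57 ± 0.25) and MVD (-1.65 ± 0.34). Camera gave an adjusted p of 7.87e-10, and 0.0464 with an estimated correlation (0.197 with letters as batches). Immediate early genes were positive in 22 of 22 with a median of 0.83, and 5 were called (13 adjusted over the list alone), with EGR1 at 2.49 ± 0.34, IER3 at 1.96 ± 0.23, SRF at 1.51 ± 0.29, ATF3 at 1.11 ± 0.22 and DUSP1 at 0.94 ± 0.22. Their adjusted p was 4.13e-10, and 0.0738 with an estimated correlation. Interferon response genes had a median of 0.93 with 16 of 17 positive and 5 called (9 higher and 1 lower adjusted over the list alone): BST2, IFI27, IFI6, IFI44L and IFI44 (2.80 ± 0.54). Their adjusted p was 5.09e-08, and 0.626 with an estimated correlation, and the medians were 0.71 for letters a and b (adjusted p = 0.000136, and 0.876 with an estimated correlation) and 1.44 for letters c and d (4.75e-12 and 0.256). Cytosolic ribosomal protein genes were positive in 51 of 52 with a median of 0.20 and 0 called, with RPLP2 at 2.34 ± 1.13 and RPL27A at 2.30 ± 0.94. Their adjusted p was 0.00442, 0.909 with an estimated correlation, 0.743 after quantile normalization and 0.0617 without the filter. It was 0.0902, 0.182 and 0.0667 without non-side population replicates a, b and d, 0.0752 without unsorted replicate b, and 0.95 for letters c and d. G2/M and mitosis genes were not called (median -0.09, adjusted p = 0.478), and for all 19 lists not called the adjusted p ranged from 0.136 to 0.894.

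Both sorted populations stood apart from unsorted cells in overlapping sets of genes. The 2 contrasts shared 191 called genes, 150 higher and 41 lower in both, with 41 called only for side population cells, 157 only for non-side population cells and 0 in opposite directions. Being called in 1 contrast alone does not show that the populations differed, and the direct comparison called 0 genes by limma. Fold changes correlated at 0.89 across genes, which are not independent replicates. Because both contrasts use the same unsorted arrays, unchanged groups were simulated on all arrays, with the simulated unsorted arrays shared by both contrasts. Noise was drawn independently for each gene and array. The correlation was then 0.666 on average over 50 simulations. The share of genes of the same sign was 73.1% against 83.0% observed, and the covariance 0.089 against 0.294. Independent lists of these sizes would share 4.24 higher and 0.611 lower genes. The 2 unsorted arrays were not divided between the contrasts, which would leave 1 for each, so part of the excess may come from the shared controls.

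**Figure D3:**
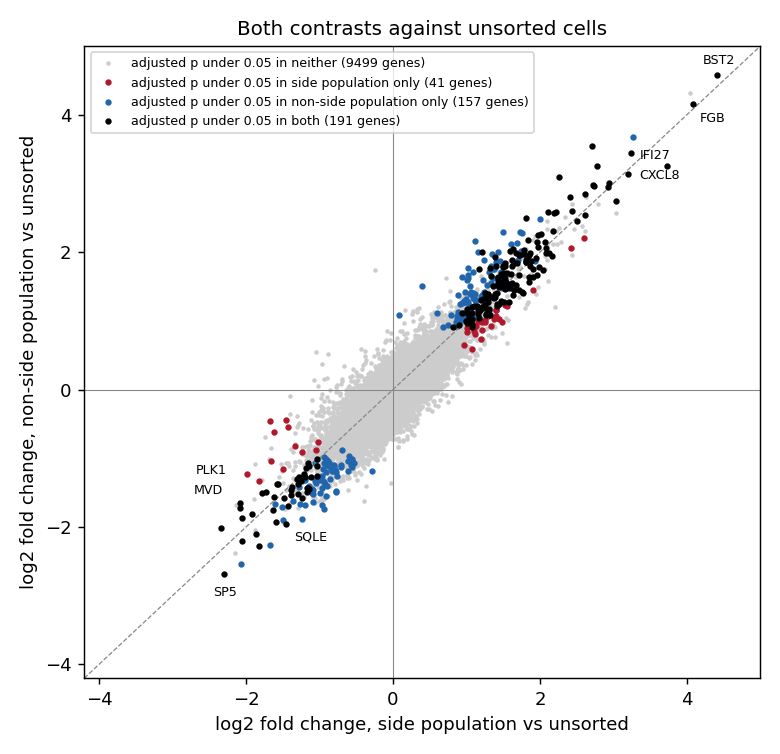
Log2 fold change against unsorted cells for 9888 genes, side population on the horizontal and non-side population on the vertical axis, with 1 point per gene coloured by the contrasts in which its adjusted p was under 0.05. The 191 genes called in both lie in the upper right and lower left along the dashed line of equal change, with BST2 and FGB at the upper end and SP5 at the lower end; both axes share the unsorted arrays.

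Stem cell and pathway genes were also set against unsorted cells. SMO, which lay below the filter, was at 2.61 ± 0.43 in side population cells (adjusted p = 0.0155) and 2.38 ± 0.43 in non-side population cells (adjusted p = 0.016) in limma without the filter. It read 17.2 and 23.1 in unsorted cells, below the array medians of 60.9 and 58.7 and with no detection calls, so these sizes depend on the constant. With values raised to the array medians they were 1.28 and 1.05. FZD7 was at 1.08 ± 0.28 (adjusted p = 0.0554) and 0.55 ± 0.28 (adjusted p = 0.294), ADAM17 at 0.85 ± 0.24 (adjusted p = 0.0759) and 0.69 ± 0.24 (adjusted p = 0.127), HEY1 at 0.86 ± 0.31 (adjusted p = 0.153) and 0.85 ± 0.31 (adjusted p = 0.144), and SOX2 at -1.50 ± 0.52 (adjusted p = 0.144) and -1.18 ± 0.52 (adjusted p = 0.23), none of which passed. A probe set of ADAM17 had the opposite sign in both contrasts. LGR5 was at -0.16 ± 0.28 and -0.42 ± 0.28, and CD44 at -0.13 ± 0.36 and -0.21 ± 0.36. Without the filter, ABCG2 was at -0.01 ± 0.82 and -0.31 ± 0.82, ABCB1 at 0.76 ± 0.61 and 0.74 ± 0.61, PROM1 at 0.42 ± 0.60 and -1.05 ± 0.60, and MSI1 at 0.69 ± 0.57 and 0.60 ± 0.57, and none of these passed either.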

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

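The tests of an unsorted mixture, of 18S ribosomal RNA and of handling before lysis, and those that divide the arrays by letter, were chosen after the results were seen; the counts over other splits of the arrays were not.

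In both sorted populations 191 genes differed from unsorted cells in the same direction, 150 higher and 41 lower, among them BST2, IFI27, IER3 and SQLE. Unsorted cells hold both populations, so a plain mixture would lie between them and share few such genes. Unchanged groups, simulated with unsorted arrays shared by both contrasts, had 0 such genes on average by limma. The simulated noise was drawn independently for each gene and array, so a count near 0 was likely from the start. The 191 genes therefore go against a plain mixture only if the unsorted arrays carry no shift common to many genes, which was not tested. RNA preparation marked by the 18S signal is argued against as the whole cause for called genes. On 247 genes called without the sorted arrays of low 18S signal, these arrays were placed where 0 is unsorted and 1 the other sorted arrays. They lay at a median position of 0.78 (side population replicate d) and 0.94 (non-side population replicate c). The positions do not cover RPL27A and RPLP2, which were not called and read lowest on these arrays within their populations. Staining, sorting or waiting before lysis stays open, since the labels place all sorted arrays and no unsorted array after a sort, and the immediate early genes, with a median log2 fold change of 0.90 in side population cells, had no mock-sorted control. A separate culture or hybridisation of the unsorted arrays, and cells outside both sorting gates, also stay open, as no array holds them apart, and the hybridisation control bioB read 813 to 1651.9 on the 8 sorted arrays and 556.2 and 660.2 on the unsorted ones, while cre overlapped.

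The difference between side and non-side population was set against all 35 splits of the 8 sorted arrays into 4 and 4. With 0 genes called for the real groups, any split reaches that count (35 of 35), so the count decides nothing about chance. The highest other split called 927 genes. That split set the arrays of letters a and b against those of letters c and d, which points to a structure of the samples, and the other 34 splits called 0; within-letter values are 905 and 0. As many lists as the real 1 were called in 34 of 35 splits, the highest other calling 8, and 18 splits called the G2/M and mitosis list, so chance cannot be excluded for it either.

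Effects that differed between groups were these. The difference of the side and non-side population effects against unsorted cells is the direct comparison of the populations, so for the G2/M and mitosis list it repeats that result and adds nothing to it (camera adjusted p = 1.17e-06, 0.946 with an estimated correlation). The difference between side and non-side population was not alike in letters a and b and in letters c and d for oxidative phosphorylation (camera adjusted p = 5.12e-12), G2/M and mitosis (0.0167), the Wnt pathway (0.0462) and cytosolic ribosomal proteins (0.0462), with adjusted p between 0.883 and 0.946 with an estimated correlation.

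The 5' control probe set of 18S ribosomal RNA, which is not part of the gene comparisons, averaged 21700 on the 8 sorted arrays and 551 on the 2 unsorted arrays. The sorted arrays were not alike: side population replicate d read 851.2 and non-side population replicate c 563, near the unsorted 274.6 and 828.3. The 3' probe set of 18S read 21976.4 to 49092.1 on the sorted arrays, and 33883.6 and 33808.8 on the unsorted ones.

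Some arrays lay far from the other 3 of their group. Of 292 groups of 4 values examined, 19 held such an array, where chance gives 14.6, so most of these are no more than chance would give: non-side population replicates b and c held 6 each, side population replicate a 4, and side population replicates b and c and non-side population replicate a 1 each. In log2 intensity, non-side population replicate b was apart for CEACAM5 (10.22), FGB (9.485), DHCR7 (8.699) and ANKRD37 (10.07), and in the mean of intestinal differentiation genes (10.22) and of MKN45-linked genes (11.75). Non-side population replicate c was apart for NDRG1 (10.28), RPL29 (14.21), RPL39 (15.11), RPL18 (14.95) and CDK1 (13.44), and in the mean of cytosolic ribosomal protein genes (14.28). Non-side population replicate a was apart for PPM1D (8.624). Side population replicate a was apart for GADD45A (12.94), the mean of p53 targets (11.29), and the 3' to 5' ratios of actin (3.34) and GAPDH (1.87). Side population replicate b was apart for REM2 (7.571) and replicate c for the mean of stem cell markers (11.76).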

How the results depend on the processing

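The division by letters was chosen after seeing the data, so fits with it may understate the spread and call too many genes. Leaving out 1 array gave 0 genes throughout and 1 to 5 lists between side and non-side population, 10 to 385 genes and 4 to 6 lists for side population against unsorted cells, and 20 to 651 genes and 3 to 5 lists for non-side population against unsorted cells; an unsorted array left alone was assumed to vary like the other groups. In the order side population and then non-side population against unsorted cells, counts were 100 and 144 with a filter at the 75th percentile, which tests fewer genes, and 904 and 1583 with every probe set, which tests more. They were 397 and 185 with only the 2 groups compared, 1327 and 1564 with letters as batches, and, against the same 2 unsorted arrays, 1359 and 2198 for sorted arrays of letters a and b and 840 and 1179 for those of letters c and d; the cause was not tested. Side population against unsorted cells gave 90 genes with only AGS-labelled arrays, which are fewer. Between side and non-side population, letters a and b gave 905 genes; lists numbered 5 with AGS-labelled arrays, 3 within letters c and d, and 0 with an estimated correlation or with fry. Against unsorted cells an estimated correlation left 1 list in each contrast and fry left 2. All other settings kept each count within 1.5 times and each list count likewise. The letters a to d as a replicate block gave 0 genes (442 at an unadjusted p under 0.05) and 1 list. Titles place side and non-side population arrays of the same letter in a replicate group of the same name, without saying what they share. Deviations of same-letter arrays correlated at 0.21, 0.50, -0.12 and 0.36, and those of different letters at -0.48 to 0.43. These values do not decide whether the letters are pairs, and the main test was unpaired. Of the called genes followed over the alternatives, none reversed. HMOX1 and AXIN2 in side population cells, and CTNNB1 and DUSP1 in non-side population cells, were named but not followed. Over 806 values of 38 genes for side population and 818 of 38 for non-side population against unsorted cells, 158 and 95 lost the call. Of these losses, 63 came without unsorted replicate a, 61 without b and 21 with only AGS-labelled arrays. For side population cells DUSP1 lost it in 12 of 22 settings, HES1 in 11, and ATF3 and PFKFB3 in 10; for non-side population cells SOD2 lost it in 12 of 21 and PFKFB3 in 13 of 22. Low intensity limits PROM1, MSI1, ABCB1, ABCG2 and SMO, which lay below the filter, and the size of change of 10 of 232 and 12 of 348 called genes, FGB among them, whose unsorted mean lay below the array medians.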

Other observations

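The tests that divide the arrays by letter were chosen only after the result was seen, and the lists described here were picked from those tested after their values were known.

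Of 18 Wnt pathway genes, limma called 2 higher and 3 lower in each sorted population than in unsorted cells. In side population cells SP5, DKK1 (-1.63 ± 0.34), a secreted inhibitor of the pathway, and AXIN2 (-1.03 ± 0.26), a feedback inhibitor, fell, and CTNNB1 (1.31 ± 0.27), which encodes beta-catenin, and FZD4 (1.65 ± 0.32), a receptor, rose; in non-side population cells DKK1 was at -1.76 ± 0.34, AXIN2 at -1.26 ± 0.26, CTNNB1 at 1.18 ± 0.27 and FZD4 at 1.45 ± 0.32 (log2 fold change ± SE, n = 4 and 2). Camera did not call the list (adjusted p = 0.867 and 0.6), its median of 0.01 and mean of -0.05 in side population cells differing in sign. A second probe set of FZD4 was at -0.43 in side population cells. HES1, a Notch target, fell in both (-1.38 ± 0.33 and -1.47 ± 0.33), and NUMBL was at 1.25 ± 0.35 (adjusted p = 0.0724) and 1.4 ± 0.35 (adjusted p = 0.0403), within a Notch list that was not called (adjusted p = 0.295 and 0.551).

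Single members of other lists that were not called also passed the test against unsorted cells. TFF1, a peptide of gastric mucus, rose by a log2 fold change of 1.36 ± 0.27 in side population and 1.51 ± 0.27 in non-side population cells against unsorted cells, and CEACAM5, an adhesion protein of gut epithelium, by 2.44 ± 0.39 and 2.60 ± 0.39, with another of its probe sets at -0.69 and -0.63. The gastric list of 4 tested genes was not called (adjusted p = 0.152 and 0.136), nor was the intestinal one (0.989 and 0.847). With letters as batches the gastric list was called (adjusted p = 0.0229 and 0.0263). For letters c and d its medians were 1.28 and 1.33 (adjusted p = 0.000492 and 0.0012), and for letters a and b 0.09 and -0.14 (0.804 and 0.71). With an estimated correlation the calls were lost, at adjusted p of 0.294 and 0.29 with batches and 0.127 and 0.111 for letters c and d. GADD45A, a stress gene of the p53 list, rose by 1.29 ± 0.26 and 1.39 ± 0.26, while the p53 list was not called (adjusted p = 0.391 and 0.489). BAX fell in side population cells (-1.46 ± 0.33, adjusted p = 0.0381) and was at -0.44 ± 0.33 (adjusted p = 0.502) in non-side population cells, a difference that did not pass between the populations themselves. EGLN3, an oxygen sensor, fell by 1.61 ± 0.32 and 1.57 ± 0.32 on the log2 scale, and PFKFB3, a regulator of glycolysis, rose by 1.16 ± 0.28 and 1.10 ± 0.28, with the hypoxia and glycolysis list not called (adjusted p = 0.645 and 0.659). HMOX1, heme oxygenase, fell in side population cells (-1.50 ± 0.33, adjusted p = 0.0312) and was at -1.15 ± 0.33 (adjusted p = 0.0679) in non-side population cells, within an NRF2 list that was not called (adjusted p = 0.471 and 0.847).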
